A study of Mus musculus with 59 samples.

How the data were processed

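Chromatin immunoprecipitation sequencing of H3K27me3, H3K27ac and H3K4me3 was carried out on snap-frozen brainstem tumours and on cultured neurospheres, per the labels' protocols. Chromatin of Drosophila S2 cells was added before immunoprecipitation, per the labels' protocols. No spike-in scale factor was among the files used here, so no value below measures the absolute amount of a mark. The submitters' processing notes name BWA 0.7.12, Picard, SAMtools, R 2.14.0, MACS2, SICER 1.1 and bedtools 2.25.0, with no role or order, and build mm9. Each deposited list came from 1 sample, with no pooling of replicates.

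The deposited H3K27me3 lists (20) follow the layout of SICER islands, with a window of 200 bp and a gap of 600 bp per the file names. Their value is the count of whole reads in each island, as deposited by the authors. Island ends are the last base of a window, so 1 base was added for lengths. A region without an island has no count in these lists. The deposited H3K27ac (11) and H3K4me3 (5) lists follow the narrowPeak layout. Per the layout of the deposited lists, each peak carries a score, a fold enrichment ratio, a -log10 p-value and a -log10 q-value from the authors' peak caller, with -log10 q of 2 or more in every list. The summit offset, another column of the deposited lists, was not used. These are the peak's own values and were used only to filter or rank peaks within a list. The other 23 samples, all input DNA, were not analysed here.

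Samples were grouped by the genotype, tissue and antibody in the labels. The labels give each tumour its own number and each neurosphere culture of a group its own letter, without saying that these came from separate animals or embryos, so p-values measure the spread between these samples. Forebrain and hindbrain K27M cultures share letters and experiment numbers. Island lists give neither total depth nor background, so a longer covered length can come from deeper sequencing as well as from more marked chromatin. Covered length was the summed length of islands, or of peaks after merging overlaps. Intervals of all libraries of a comparison were merged where they shared 1 bp. A library called a region when it held an interval there. Groups were compared by a two-sided exact permutation test of mean log2 values. Calls were compared by Fisher's exact test per region, with Benjamini-Hochberg adjustment over regions whose number of calls could give an unadjusted p under 0.05. Reads inside islands were summed per region, over regions called in every library of the comparison. These sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, Benjamini-Hochberg, threshold 0.05) in R 4.3.3. CPM values are relative to reads in those common regions. The SE of a log2 fold was derived from the F statistic. The SE of a difference within sex came from the spread inside the 4 groups of sex and genotype, and that of a pooled difference from the spread of each genotype. DESeq2 1.42.0 served as an alternative. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

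Island reads per kb over total island reads, which had been planned for tumours, is the inverse of covered length by its definition and was not analysed separately. H3K4me3 peaks of the 5 tumours were merged into 41271 intervals to describe other regions. WT read density was the mean reads per kb of island over WT libraries. Regions kept or lost as calls were merged over all 6 hindbrain libraries, which gives 1652 X and 9372 autosomal regions called by both female WT libraries. Retention by WT density used regions merged over WT libraries alone. For the density quartiles and the matched X regions these were the 2 female WT libraries, which gives 1803 X regions. Expected overlap assumed H3K27ac placed evenly over 2639 Mb.

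The rule for named items was fixed before the data were examined. It took 5 regions per direction by absolute log2 fold past the threshold in read tests, and 5 per direction among fully separated calls. Of the latter the first 1 or 2 are printed. Also printed are the K27M-only H3K27ac peak ranked 4, which lies beside the first, and the 3 widest shared H3K27ac sites. No gene annotation of build mm9 was given, so regions are named by position. The gene lists and cell type markers fixed beforehand could not be applied, and what lies at each position (gene, exon, intron or UTR) is not stated.

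Experiment numbers pair the neurosphere libraries, since the labels give each an experiment id that is shared across groups. Deviations of same-numbered libraries from their group means correlated at 0.20, 0.23 and 0.21 between forebrain and hindbrain K27M, and at 0.10, -0.03 and 0.02 between hindbrain K27M and WT. The fit with experiment as a block was an alternative.

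After the data were seen, 14 further measures that set marks or systems against each other were tested, with Benjamini-Hochberg adjustment over the 14. The share of reads in the strongest islands was also added then. Alternatives were a higher threshold, a minimum width, autosomes alone, other summaries, other scaling and count minima, sex, the experiment block and leaving out each library. The read test was tested on simulated reads for the regions of each comparison with 200 regions changed. At a 2-fold change it recovered 37.0% of changed regions in tumours (3067 regions), 54.0% in hindbrain (3334 regions) and 77.0% in forebrain against hindbrain (3363 regions). At a 4-fold change it recovered 90.0%, 96.0% and 99.0%. False calls made up 5.22%, 5.06% and 3.30% of calls. The simulated changes were balanced between directions and left the islands as called. These rates may therefore not hold where changes are many, uneven or tied to island length. The Fisher step, on 11000 simulated regions without a difference, passed 0 of 4103 tested, with 62 at an unadjusted p under 0.05.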

Results

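The series profiled histone H3 marks by chromatin immunoprecipitation and sequencing in a mouse knock-in model of the K27M change in the histone gene H3f3a, compared with a matched knock-in of the tagged wild-type histone (WT). H3K27me3 is the repressive mark laid down by Polycomb repressive complex 2, H3K27ac marks active promoters and enhancers, and H3K4me3 marks promoters. Processed lists of 36 of the 59 samples were analysed, and the other 23 samples were input DNA. Brainstem tumours arose in mice that also carried a mutant PDGFRα transgene and a conditional loss of Trp53. H3K27me3 and H3K27ac were profiled in 6 K27M and 5 WT tumours, and H3K4me3 in 2 K27M and 3 WT tumours. Neurospheres, which are floating cultures of neural precursors, came from embryonic hindbrain (3 K27M and 3 WT libraries) and forebrain (3 K27M libraries), with H3K27me3 profiled in each. The H3K27me3 lists held 3208588 to 16323822 reads inside islands per library. The H3K27ac lists held 36284 to 61251 peaks and the H3K4me3 lists 28480 to 34291 peaks. Total sequencing depth was not given in the sources used here, and positions are in mouse build mm9, counted from 1.

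In hindbrain neurospheres, H3K27me3 islands covered much less of the genome in K27M than in WT cells. On the autosomes, islands covered 42.7 Mb ± 4.71 (SD, n = 3) in K27M and 161.8 Mb ± 25.0 (SD, n = 3) in WT, and the highest K27M library lay at 45.6 Mb against 144.9 Mb for the lowest WT library. Over all chromosomes the lengths were 91.7 Mb ± 9.34 (SD, n = 3) and 205.5 Mb ± 12.6 (SD, n = 3), a 0.445-fold ratio. The number of islands was 9708 ± 900 (SD, n = 3) in K27M and 19221 ± 552 (SD, n = 3) in WT. The groups did not overlap in any of these measures, and the two-sided exact permutation test gave p = 0.1 for the total length, the smallest value that 3 against 3 libraries can give. By a measure chosen after the data were seen, the 1000 strongest autosomal islands held 84.4% ± 1.79 (SD, n = 3) of autosomal island reads in K27M and 50.7% ± 1.08 (SD, n = 3) in WT. This share rises when weak islands drop out of a list. Over the 6020 strongest islands of every library it was 84.9% ± 1.52 (SD, n = 3) and 62.5% ± 0.683 (SD, n = 3). The WT library of experiment 3 was labelled male and the other hindbrain libraries female, and without that experiment the autosomal lengths were 41.2 Mb ± 5.60 (SD, n = 2) and 147.5 Mb ± 3.67 (SD, n = 2).

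**Figure D1:**
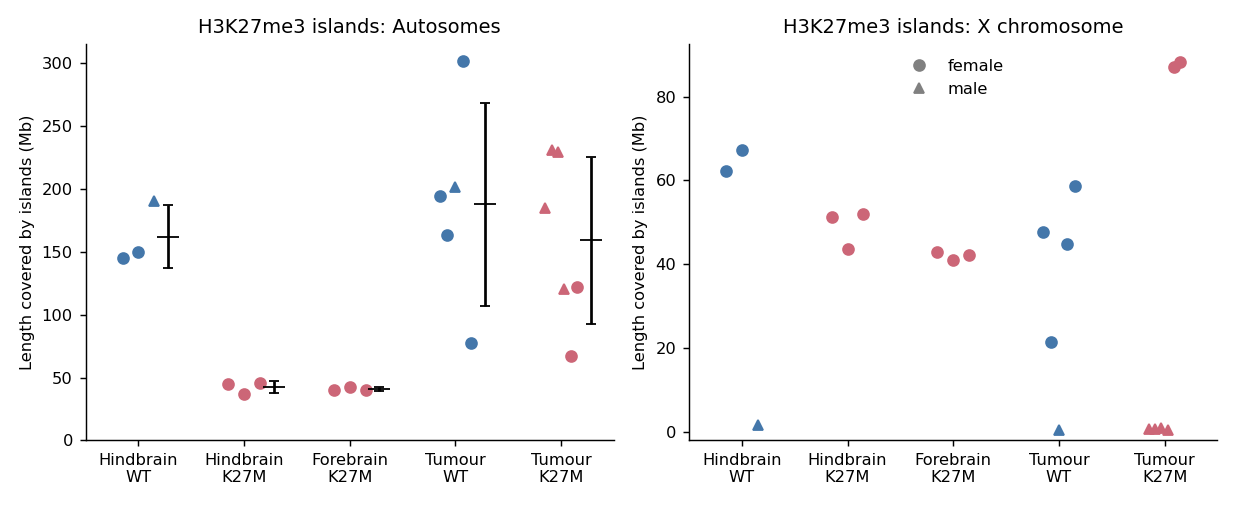
Length covered by H3K27me3 islands in Mb, on autosomes (left) and on the X chromosome (right), 1 symbol per library (circles female, triangles male); bars on the left show mean ± SD of each group, and none are drawn for X because groups mix sexes. The 3 hindbrain K27M libraries lie between 37.3 and 45.6 Mb on the autosomes, below the 3 WT libraries at 144.9 to 190.6 Mb.

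The regions that lost their island in K27M hindbrain cells were narrower and less densely marked in WT than those that kept one. Most of those that kept one overlapped a tumour H3K4me3 peak. Of 23562 merged regions, 3877 held an island in all 3 WT and no K27M library, 46 showed the opposite, and 3334 held one in all 6 libraries. Chance gives 10% of fully separated calls among regions called in 3 of 6 libraries. The lost regions had a median width of 10.4 kb and a median of 25.0 WT reads per kb, and 28.1% overlapped an H3K4me3 peak of any tumour. The regions kept in all 6 libraries had a median width of 19.1 kb and 41.9 WT reads per kb, and 73.3% overlapped an H3K4me3 peak. Of all merged regions 27.1% did, close to the lost ones, and these shares were not adjusted for width. The median width of all merged regions was 7.20 kb, below that of the lost ones. An island over 1 bp was enough to keep a region, which favours wide regions. Each K27M library retained 42.5% to 50.5% of the 8917 regions called by all WT libraries. Retained regions exceeded lost ones in WT read density by 0.59 ± 0.04 on the log2 scale (SD, n = 3 libraries). The 46 regions called only in K27M had a median width of 4.20 kb.

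Within the 3334 regions that all 6 hindbrain libraries marked, island reads shifted between regions. Only reads inside called islands are counted. The median called length per common autosomal region was 5.80 to 7.20 kb in K27M and 14.4 to 16.6 kb in WT. A region can therefore fall because parts of it no longer passed as islands. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 863 regions rose and 946 fell in K27M relative to the other common regions. The regions that rose were already the denser ones in WT, with a median of 7.22 CPM per kb against 4.10 for those that fell, where CPM is relative to the reads in common regions. An H3K4me3 peak lay in 81.9% of the regions that rose and in 70.4% of those that fell (Fisher's exact test, p = 9.5e-09, across regions, which are not independent). Of the regions called in neither direction 70.3% held one, close to those that fell. The largest increase was at chromosome 2, 147006601 to 147029000, with 1413 ± 154 CPM (SD, n = 3) in K27M and 58.8 ± 52.9 (SD, n = 3) in WT, a log2 fold of 4.58 (SE 0.89, edgeR adjusted p = 0.00554). Increases of 3.29, 3.28, 3.24 and 3.22 followed at chromosome 8, 48492001 to 48499000, chromosome X, 55263201 to 55299200, chromosome 14, 122763801 to 122794800, and the neighbouring chromosome 14, 122845401 to 122901600. The largest decrease was at chromosome 5, 139340601 to 139440000, with 11.9 ± 3.76 (SD, n = 3) against 275.8 ± 51.6 (SD, n = 3) CPM, a log2 fold of -4.54 (SE 0.29, edgeR adjusted p = 0.000136). Decreases of -4.49, -3.44, -3.42 and -3.42 followed at chromosome 18, 4797601 to 4858000, chromosome 2, 28587401 to 28630000, chromosome 6, 49165001 to 49183800, and chromosome 4, 117023401 to 117074600. Scaling to total reads in common regions, without composition factors, gave 319 higher and 2129 lower regions and moved the median log2 fold of all regions from -0.11 to -1.02, so the split between directions rests on the scaling.

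The X chromosome lost less of its island length than the autosomes in female K27M hindbrain cells. Its share of island reads did not rise. In the female experiments, X islands covered 47.5 Mb ± 5.39 (SD, n = 2) in K27M and 64.7 Mb ± 3.51 (SD, n = 2) in WT, a 0.733-fold ratio, against 0.278-fold on the autosomes. The X held 32.6% and 30.7% of island reads in WT and 32.0% and 27.9% in K27M in experiments 1 and 2. With regions merged over all 6 hindbrain libraries, both K27M libraries kept 57.5% of the 1652 X regions marked in both WT libraries and 38.1% of the 9372 autosomal ones. With regions merged over the 2 female WT libraries alone, and among their densest quartile, K27M islands covered 97.1% and 90.9% of the X length in experiments 1 and 2, and 53.9% and 49.2% of the autosomal length. With 2 libraries per group the smallest p that a permutation can give is 0.333, and the comparison of X with autosomes was chosen after the data were seen.

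**Figure D2:**
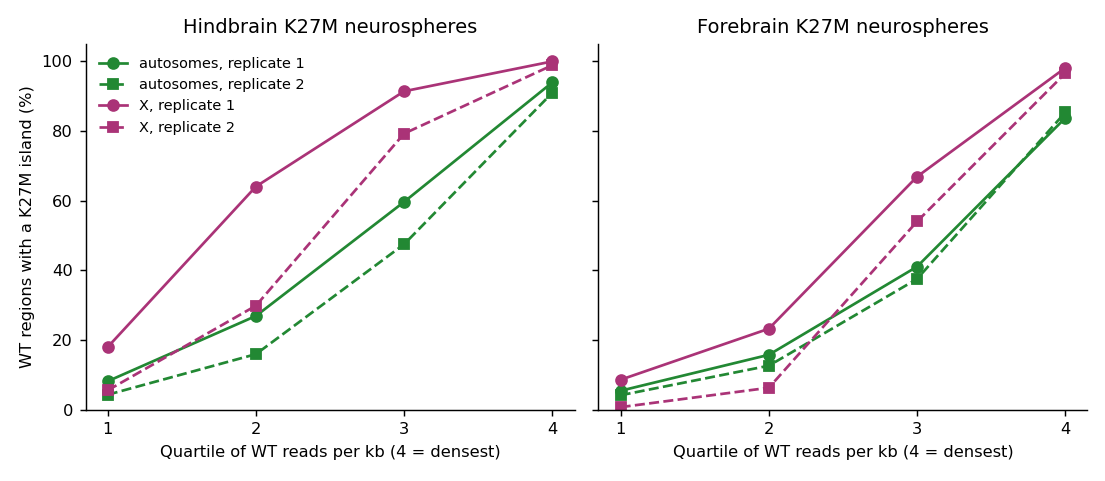
Percent of regions marked in both female WT hindbrain libraries that hold an island in a K27M library, by quartile of WT read density, for autosomes (green) and X (purple) in hindbrain (left) and forebrain (right) neurospheres of experiments 1 and 2. In hindbrain, retention climbs from 8.20% and 4.33% of autosomal regions in quartile 1 to 94.0% and 91.0% in quartile 4, and the X curves lie above the autosomal curves; in forebrain experiment 2, X lies below the autosomes in quartiles 1 and 2 (0.761% against 4.18% in quartile 1).

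Forebrain and hindbrain K27M neurospheres were not told apart by the total length of marked genome but differed at many single regions. Islands covered 82.8 Mb ± 0.601 (SD, n = 3) in forebrain and 91.7 Mb ± 9.34 (SD, n = 3) in hindbrain, which did not differ by more than the spread (exact permutation test, two-sided, p = 0.4, smallest possible 0.1). The number of islands did not overlap, at 7592 ± 611 (SD, n = 3) in forebrain and 9708 ± 900 (SD, n = 3) in hindbrain (exact permutation test, p = 0.1, the smallest possible). Of 3363 regions marked in all 6 libraries, 522 rose and 535 fell in forebrain relative to hindbrain by edgeR's test. On the X chromosome lay 8 of those that rose, 172 of those that fell and 599 of the 2306 called in neither direction. With the 2584 autosomal regions alone, 451 rose and 488 fell. The largest forebrain excess was at chromosome 8, 94311601 to 94338200, with 1516 ± 81.9 CPM (SD, n = 3) in forebrain and 19.9 ± 8.73 (SD, n = 3) in hindbrain, a log2 fold of 6.25 (SE 0.30, edgeR adjusted p = 8.8e-06). Chromosome 13, 78296801 to 78357400, stood at 3226 ± 543 (SD, n = 3) against 50.1 ± 13.9 (SD, n = 3), the second largest log2 fold. Log2 folds of 4.96, 4.52 and 4.46 were found at chromosome 14, 49258001 to 49305400, chromosome 1, 191986601 to 192004000, and chromosome 15, 25208601 to 25231600. The largest hindbrain excess was at chromosome 2, 38175801 to 38231200, with 120.2 ± 34.8 (SD, n = 3) in forebrain and 4305 ± 581 (SD, n = 3) in hindbrain, a log2 fold of -5.16 (SE 0.24, edgeR adjusted p = 7.3e-06). Log2 folds of -3.99, -3.87, -3.82 and -3.72 were found at chromosome 12, 31067801 to 31100800, chromosome 1, 76918201 to 76956000, chromosome X, 90519401 to 90588800, and chromosome 5, 15479401 to 15503000. No WT forebrain library was among the samples analysed here, so this is a difference between brain regions within K27M.

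In brainstem tumours, the length of genome under H3K27me3 islands did not separate K27M from WT. For the share of reads in the strongest islands, a measure chosen after the data were seen, the outcome depended on how the lists were matched. Islands covered 188.8 Mb ± 44.3 (SD, n = 6) in K27M tumours and 222.4 Mb ± 79.2 (SD, n = 5) in WT tumours (exact permutation test, two-sided, p = 0.463). The 1000 strongest autosomal islands held 44.3% ± 8.74 (SD, n = 6) of autosomal island reads in K27M and 30.8% ± 4.02 (SD, n = 5) in WT tumours (exact permutation test, p = 0.013). The lists differ in length. Over the 10716 strongest islands of every tumour the share was 50.4% ± 3.67 (SD, n = 6) and 38.8% ± 2.15 (SD, n = 5) (exact permutation test, p = 0.00216, the smallest possible). Over the strongest islands up to 67.1 Mb in every tumour it was 68.2% ± 8.03 (SD, n = 6) and 61.9% ± 16.3 (SD, n = 5) (exact permutation test, p = 0.411). With genotype permuted within sex the unmatched share gave p = 0.04 (exact permutation test, 75 arrangements). In females alone its log2 difference was 0.87 (exact permutation p = 0.0667, the smallest that 2 against 4 can give). The 1 WT male, at 35.2%, lay inside the range of the 4 K27M males, 34.5% to 48.3%. Of the K27M tumours 4 were male and 2 female, and of the WT tumours 1 was male and 4 female. Among females, autosomal islands covered 94.5 Mb ± 38.8 (SD, n = 2) in K27M and 184.4 Mb ± 92.7 (SD, n = 4) in WT tumours, which overlapped (exact permutation test, p = 0.267, smallest possible 0.0667).

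Among the 3067 regions that all 11 tumours marked, 218 rose and 143 fell in K27M tumours by edgeR's test. Regions that rose were wide, with a median of 49.5 kb, and 96.8% of them held an H3K4me3 peak of any tumour. Regions that fell had a median of 36.8 kb, and 79.0% held such a peak (Fisher's exact test between the 2 sets, p = 7.0e-08, across regions). Regions called in neither direction had a median of 30.4 kb, and 83.6% held such a peak. These shares were not adjusted for width. The largest increase was at chromosome 16, 91156001 to 91248600, with 890.6 ± 262.8 CPM (SD, n = 6) in K27M and 153.6 ± 130.4 (SD, n = 5) in WT tumours, a log2 fold of 2.54 (SE 0.55, edgeR adjusted p = 0.0115). Chromosome 4, 99220601 to 99383400, rose by a log2 fold of 2.49 and chromosome 6, 114209001 to 114246600, by 2.32. At chromosome 6, 53742801 to 53783200, the counts were 209.1 ± 51.6 (SD, n = 6) and 43.7 ± 15.6 (SD, n = 5), a log2 fold of 2.26 (SE 0.30, edgeR adjusted p = 0.000869). The fifth was chromosome 11, 61409801 to 61464400, with a log2 fold of 2.23, where the groups overlapped. All 5 of these regions held an H3K27ac peak in each of the 11 tumours and an H3K4me3 peak in each of the 5 tumours profiled for it. They are 37.6 to 162.8 kb wide, and a peak anywhere inside counts. How often other common regions held H3K27ac was not computed, so this is not shown to be particular to regions that rose. The clearest decrease was at chromosome 11, 55407801 to 55461200, with 75.2 ± 24.0 (SD, n = 6) in K27M and 367.2 ± 69.4 (SD, n = 5) in WT tumours, a log2 fold of -2.29 (SE 0.26, edgeR adjusted p = 0.00058). The other named decreases, -2.45 at chromosome 5, 134179801 to 134329400, -2.36 at chromosome 3, 83384601 to 83456200, -2.35 at chromosome 5, 116886601 to 117055200, and -2.33 at chromosome 11, 99450201 to 99503200, had groups that overlapped. Of the 10 named regions, 4 lost their call in some alternatives. These were chromosome 5, 134179801 (6 of 17), chromosome 3, 83384601 (3 of 18), chromosome 11, 99450201 (8 of 17), and chromosome 11, 61409801 (2 of 17). With sex as a covariate 295 regions were called, 248 of them among the 361. The chromosome 11 decrease at 99450201 lost its call (log2 fold -2.17, adjusted p = 0.0618, range over its alternatives 0.000504 to 0.104). Without K27M tumour 6 the total number of calls was 235 and without WT tumour 7 it was 238. DESeq2 called 634, and scaling without composition factors gave 158 higher and 300 lower regions and moved the median log2 fold from -0.10 to -0.29.

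As calls, present or absent, few tumour regions separated the genotypes. Of 57859 merged H3K27me3 regions, 48 were called in all 6 K27M and no WT tumour and 47 in all 5 WT and no K27M tumour. This balance depended on the lists: with the same number of top-ranked islands in every tumour the counts were 128 and 27, and without WT tumour 11 they were 55 and 245. None of the 11285 regions tested passed the adjusted threshold by Fisher's exact test, and 676 had an unadjusted p under 0.05 (1753 without WT tumour 11). The K27M-only regions with most reads were at chromosome 11, 61363201 to 61407200, with 6025 reads over the 6 tumours, and chromosome 15, 100583801 to 100632000, with 3427 reads. The first of these lies next to the chromosome 11 region that rose in read counts. The WT-only region with most reads was at chromosome 11, 55910401 to 55951000, with 2822 reads over 5 tumours.

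The lengths covered by H3K27ac and H3K4me3 did not differ between genotypes by more than the spread between tumours. H3K27ac peaks covered 36.0 Mb ± 7.10 (SD, n = 6) in K27M and 39.3 Mb ± 9.44 (SD, n = 5) in WT tumours (exact permutation test, two-sided, p = 0.541). H3K4me3 peaks covered 38.9 Mb ± 0.732 (SD, n = 2) and 37.5 Mb ± 3.02 (SD, n = 3), with an exact permutation p = 0.9 where the smallest possible is 0.1. The share of H3K4me3 peaks that overlapped an H3K27me3 island of the same tumour was 26.4% ± 2.71 (SD, n = 2) and 25.7% ± 3.00 (SD, n = 3), with an exact permutation p = 0.7. Of 99012 merged H3K27ac regions, 20 were called in all K27M and no WT tumour and 10 in all WT and no K27M tumour. Which group had more was not stable: the counts were 16 and 19 with the same number of top-ranked peaks, 7 and 8 with -log10 q of at least 5, and 40 and 54 without WT tumour 8, but 49 and 17 without K27M tumour 2. None of the 14880 tested passed the adjusted threshold by Fisher's exact test, and 363 had an unadjusted p under 0.05 (1264 without WT tumour 8). The strongest WT-only peak was at chromosome 13, 40822952 to 40826435, with a mean -log10 q of 57.2 in the authors' lists. The strongest K27M-only peak was at chromosome 2, 115684390 to 115686963, with a mean -log10 q of 17.2, and another K27M-only peak lay beside it at 115681510 to 115682715.

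A larger share of H3K27ac lay inside H3K27me3 islands of the same tumour in K27M than in WT. The share of H3K27ac length inside islands was 14.2% ± 4.50 (SD, n = 6) in K27M and 6.85% ± 3.01 (SD, n = 5) in WT tumours, a 2.19-fold ratio (exact permutation test, two-sided, p = 0.0108). Over the share expected from the islands' length, H3K27ac stood at ratios of 1.55 to 2.52 in the 6 K27M and 0.397 to 1.14 in the 5 WT tumours, with no overlap between groups (exact permutation test, p = 0.00216, the smallest possible). On the autosomes the log2 difference of the share was 1.29 (SE 0.43), and as the mean of the differences within each sex 0.98 (SE 0.48; exact permutation within sex, p = 0.0533). Over the share expected, the same values were 1.52 (SE 0.38) and 1.47 (SE 0.44; exact permutation within sex, p = 0.0133, the smallest of 75 arrangements). In females the autosomal shares ranged from 7.88% to 11.8% in K27M and from 2.16% to 10.0% in WT tumours. With islands limited, after the planned result had been seen, to the 60 Mb of highest read density in each tumour, the share was 7.20% ± 0.969 (SD, n = 6) in K27M and 2.15% ± 1.26 (SD, n = 5) in WT tumours (exact permutation test, p = 0.00216, and p = 0.0133 within sex).

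**Figure D3:**
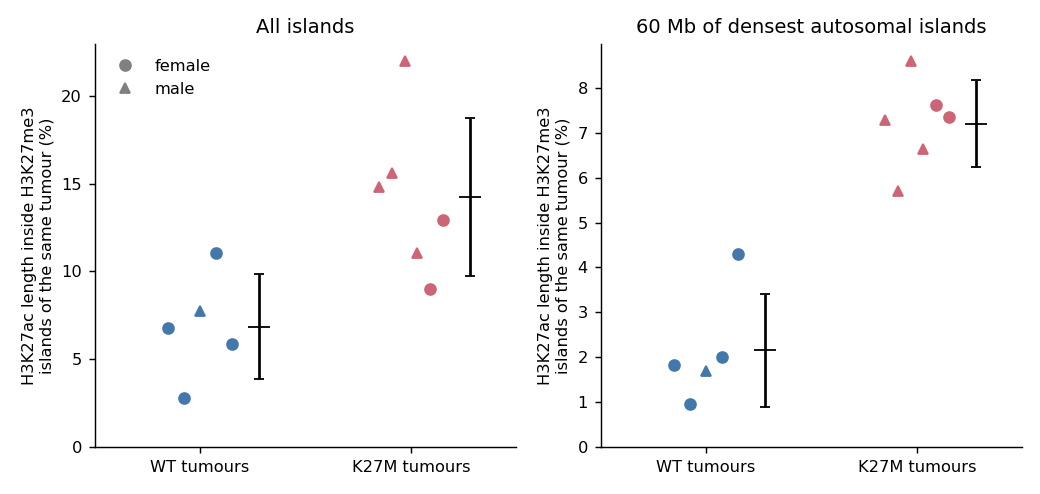
Percent of H3K27ac peak length that lies inside H3K27me3 islands of the same tumour, for all islands (left) and for the 60 Mb of densest autosomal islands with autosomal H3K27ac only (right); each symbol is 1 tumour (circles female, triangles male) and bars are mean ± SD. On the right the K27M tumours lie between 5.70% and 8.59% and the WT tumours between 0.949% and 4.29%.

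At single sites, islands lay over shared H3K27ac regions more often in K27M tumours. Of 14660 autosomal H3K27ac regions called in all 11 tumours, 56 lay in an island in every K27M and no WT tumour, and none showed the opposite. These 56 passed Fisher's exact test with adjustment over 1068 testable regions (adjusted p = 0.0413). At an unadjusted p under 0.05, 250 regions held islands more often in K27M and 4 more often in WT tumours. Per tumour, 14.4% ± 5.64 (SD, n = 6) of the 13191 regions at H3K4me3 peaks held an island in K27M and 7.94% ± 3.65 (SD, n = 5) in WT. This missed the threshold after adjustment (exact permutation p = 0.0433, adjusted 0.0606 over 14 measures). Of the other 1469 regions 8.38% ± 7.67 and 1.74% ± 2.27 did (exact permutation p = 0.026, adjusted 0.0404). The widest of the 56 were at chromosome 3, 45179889 to 45191372, chromosome 5, 22248296 to 22257832, and chromosome 1, 138122186 to 138131708, each with an H3K4me3 peak in all 5 tumours profiled for it. This set was examined after the planned comparison had been seen. Leaving out any 1 tumour left none past the adjusted threshold, with 263 to 410 regions at an unadjusted p under 0.05. With islands limited to the densest 60 Mb 257 regions passed, and with at least 50% of each region covered 55 passed.

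The sex given in the labels was visible in the H3K27me3 of the X chromosome, which in female cells carries the inactive X. The X share of island length was 31.0% ± 18.7 (SD, n = 6) in female and 0.339% ± 0.079 (SD, n = 5) in male tumours (exact permutation test, two-sided, p = 0.00216). The only WT tumour labelled male, tumour 9, had an X share of 0.238%. It had 0 Y peaks for H3K27ac and H3K4me3, unlike the male K27M tumours. Its label is thus borne out by the X alone, and tests that permute genotype within sex use it as their only WT male. In female tumours X islands covered 87.6 Mb ± 0.808 (SD, n = 2) in K27M and 43.2 Mb ± 15.6 (SD, n = 4) in WT, with an exact permutation p = 0.133 where the smallest possible is 0.0667.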

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

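Of the tests in this part, that of the median reads per region was set before its result was seen; those on islands of highest density, on H3K27ac regions common to all tumours, within sex, on matched X regions, on total reads and gains of reads in every K27M library, and on other splits of the samples were chosen after. Single values stood apart in 3 of 54 groups tested, where chance gives about 1 in 20. K27M tumour 6 had 68.7 island reads per kb, against 31.8 to 44.2 in the other K27M tumours. WT tumour 10 held 16323822 island reads, against 3208588 to 6438054 in the other WT tumours. WT tumour 11 had 2.69% of the length of common H3K27ac regions inside its densest 60 Mb of islands, against 0.983% to 1.39% in the other WT tumours. On the Y chromosome, which no comparison used, the male K27M tumours 1 and 2 had 4 H3K27ac peaks each, tumours 3 and 4 had 3 each, and tumour 2 had 3 H3K4me3 peaks. Female libraries and the library labelled male among WT tumours had 0 Y peaks for these marks.

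The larger share of H3K27ac inside H3K27me3 islands in K27M tumours could come from weakly enriched islands, from other H3K27ac peaks or from the sex make-up of the groups. Other H3K27ac peaks are argued against as the whole cause. The difference held over the H3K27ac regions called in all 11 tumours (exact permutation p = 0.00866, adjusted 0.0202 over 14 measures). It also held with the densest 60 Mb of islands (exact permutation p = 0.00216, adjusted 0.00758). That cut removes little from the shortest autosomal lists, those of K27M tumour 5 (67.1 Mb) and WT tumour 11 (77.6 Mb). Among longer lists, K27M tumours 1, 2 and 3 (184.8 to 230.9 Mb) held 5.70% to 8.59%. WT tumours 7, 8, 9 and 10 (163.5 to 302.0 Mb) held 0.949% to 2.00%. For these tumours islands of low read density are argued against as the whole cause. Density is reads per kb and was not set against input DNA, so the cut cannot exclude dense islands with weak enrichment over input. For the share over all autosomal islands sex cannot be told apart from genotype by the test within sex (exact permutation p = 0.0533): the log2 difference was 1.29 (SE 0.43) pooled and 0.98 (SE 0.48) within sex, 0.96 in females and 0.99 in males, and with 1 WT male 4 of 75 arrangements were as large. Sex is argued against as the whole cause of the share over that expected from island length (1.52 pooled, 1.47 within sex) and of the share in the densest islands (1.90 and 1.98). Each had an exact permutation p = 0.0133 within sex, the smallest of 75 arrangements. Both tests take the label of the only WT male as right, although that tumour had 0 Y peaks for H3K27ac and H3K4me3. The autosomal ratio to the share expected was highest in the shortest list of each genotype (2.91 in K27M tumour 5, 1.56 in WT tumour 11). An effect of unequal island length on that ratio is therefore not excluded. Overlap in different cells of the same tumour piece was not tested and stays open, as does an effect of K27M itself.

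Of 100 splits of the tumours, 1, the real one, gave as many regions with islands at shared H3K27ac sites (254, highest other 197). This set was chosen after the same tumours had shown the larger share, and no region passed the adjustment with any 1 tumour left out. Chance is therefore not taken as excluded for that count.

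The X chromosome of female K27M hindbrain neurospheres kept more island length than the autosomes. Its regions were wider and denser in WT, which could make islands easier to keep. Of the 1803 X regions (merged over the 2 female WT libraries), 1649 were matched to an autosomal region within 0.25 on the log2 scale in WT density and width. Islands covered at least 28.2 percentage points more of the length of the X regions than of their matches in both hindbrain K27M libraries, which argues against density and width as the whole cause; counted as calls, the shares lay closer, at 70.6% against 55.9% in experiment 1 and 57.1% against 49.6% in experiment 2. The X share of island reads did not rise (32.6% and 30.7% in WT, 32.0% and 27.9% in K27M), so the pattern holds for island length and not for reads. Only 2 WT hindbrain libraries were female, and a biological difference between the inactive X and autosomes may remain but was not tested.

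The strongest islands held a larger share of H3K27me3 reads in K27M than in WT hindbrain neurospheres. Shorter lists alone raise this share, and with 6020 islands in every library it was 84.9% against 62.5%; length could not be matched, since the strongest 37.3 Mb of 1 WT library held only 769 islands. Fewer usable reads could do this, and the median reads per common autosomal region was 0.388 of that in WT. Reads are counted only inside called islands, and this value goes with shorter called length per region (median 5.80 to 7.20 kb in K27M, 14.4 to 16.6 kb in WT), while reads per called kb were 33.8 to 39.3 in K27M and 39.0 to 45.9 in WT. Total reads in the same regions stood at 0.901 of WT, with groups that overlapped, which does not measure depth either, since called length differs between the groups. Of the 3265 common autosomal regions, 8.58% had more island reads in every K27M than in every WT library and 67.2% had fewer. Without any change 5% would be expected each way, so the same loss of island reads in every region is argued against. Regions are not independent, and no spread was computed for this share. Lower depth need not be such a loss, since it can also shorten called islands, so these values do not argue against it. How far lower depth adds to a redistribution of the mark cannot be told apart, because total depth and spike-in factors were not among the sources used here.

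The read tests were repeated on other splits of the libraries. In tumours only the real split of 100 gave as many regions (1 of 100, 361 regions against at most 155). This argues against chance but does not exclude it, since only some of the possible splits were drawn. The splits also do not account for sex, which is uneven between the groups. In hindbrain neurospheres (1809 regions, highest other 0) and in forebrain against hindbrain (1057 regions, highest other 0) the 10 splits are too few for a share under 0.05. For calls at an unadjusted p under 0.05, 7 of 100 splits gave as many H3K27me3 regions as the real one (676, highest other 1600) and 13 of 100 gave as many H3K27ac regions (363, highest other 1027), so chance is not excluded. Splits with far more regions point to other structure among the tumours, and for H3K27me3 part of it is sex: females against males gave 1803 regions, 198 of them on autosomes, and the split with 1600 regions had 268 there. On the autosomes, where all 676 lie, 4 of 100 splits gave as many (highest other 1097), but this count was chosen after the first and no region passed the adjustment, so chance is not taken as excluded. The split with 1097 sets the 6 tumours with most autosomal island length (184.8 Mb or more) against the others (163.5 Mb or less).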

How the results depend on the processing

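The share of reads in the strongest islands, scaling without composition factors, analyses of single sexes on autosomes, the 500 strongest islands, the matched lists, the fit without experiment 3 in read counts and the alternatives for shared H3K27ac sites were chosen after seeing the data. The share of H3K27ac inside H3K27me3 kept its direction and side of the threshold in all 14 alternatives, with log2 differences of 0.84 to 1.34 when single tumours were left out. The hindbrain length difference kept its direction in all 14 (-1.22 to -1.08 with a library left out), but its design cannot pass the threshold. Leaving out single libraries gave -0.36 to -0.03 for tumour H3K27me3 length, -0.21 to -0.01 for H3K27ac length, -0.0123 (without WT tumour 9) to 0.10 for H3K4me3 length, -0.0643 (without K27M tumour 2, and -0.0153 without WT tumour 7) to 0.15 for the share of H3K4me3 peaks with an island, -0.23 to -0.09 for forebrain against hindbrain, and 0.57 to 0.61 for density of retained regions. Counting H3K27ac peaks in place of length turned the H3K27ac log2 difference to 0.0467 (p = 0.781 by exact permutation), and the H3K4me3 length and the share of H3K4me3 peaks with an island turned to the values given for the tumours named; the cause was not tested. The X share differed between sexes by a log2 6.31 within WT and 7.08 within K27M tumours, where too few tumours are left to pass. The density difference of retained regions moved to 0.81 with 50% of a region covered and to 0.47 in regions of 2 to 10 kb; the cause was not tested. Tumour read calls ranged from 235 to 449 with a tumour left out (235 without K27M tumour 6 and 238 without WT tumour 7) and were 634 with DESeq2, which included all 361. Hindbrain calls ranged from 1432 to 1926 and forebrain against hindbrain calls from 734 to 1043. With uncalled regions as 0 these rose to 5334 and 2124 while tumour calls fell to 311; this setting lets more regions enter and also builds in large folds where 1 group has no island, and the 2 were not separated, so the cause was not tested. With the replicate block by experiment they were 1712 and 1280, and the hindbrain length test gave p = 0.25, the smallest possible by exact sign flips; the block changed no call of a named region and no count by over 1.5 times. Fisher calls stayed at 0 in all alternatives, with 822 to 1753 H3K27me3 and 464 to 1264 H3K27ac regions at an unadjusted p under 0.05 when single tumours were left out (1753 without WT tumour 11 and 1264 without WT tumour 8), since smaller groups change which calls can reach that p. Islands at shared H3K27ac sites numbered 263 to 410 then (410 without K27M tumour 5 and 389 without WT tumour 9). The share of tumour reads in the strongest islands passed with the same number of islands in every tumour (log2 0.38, exact permutation p = 0.00216) and missed the threshold with the same length (0.18, p = 0.411; no valid share for hindbrain, where that length holds under 1000 islands in 1 WT library) and within females (log2 0.87, exact permutation p = 0.0667) and males (0.16, p = 0.6). Of the 10 named tumour regions, 6 passed in every alternative run, and the other 4 kept their direction with adjusted p up to 0.117. These 4 lost their call with uncalled regions as 0, and also chromosome 5, 134179801, without K27M tumour 1, 5 or 6 or WT tumour 7 or 9, chromosome 3, 83384601, without WT tumour 8 or 9, chromosome 11, 99450201, without K27M tumour 1, 3, 4 or 5 or WT tumour 7 or 8 and with sex as a covariate, and chromosome 11, 61409801, without WT tumour 7; all 20 named neurosphere regions passed in every alternative run. Gene list alternatives were not run because no annotation of the build was given, nor were those of island read density, which repeats the covered length. Unknown total depth limits every length and call, since a region without an island may lie just under the caller's threshold.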

Other observations

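In this part the test with equal island length was set before its result was seen, and all others were chosen after. Tumours of both genotypes held islands more often at regions that kept H3K27me3 in K27M neurospheres than at regions that lost it. Tumour islands lay on 76.5% ± 7.93 (SD, n = 6) of the 3265 kept autosomal regions in K27M and 77.3% ± 8.96 (SD, n = 5) in WT tumours. At the 3864 lost regions the share ranged from 31.6% to 66.3% in the 6 K27M and from 39.3% to 81.1% in the 5 WT tumours. The log2 difference between genotypes was -0.01 at kept and -0.22 at lost regions, neither beyond the spread (exact permutation p = 0.887 and 0.392). The odds of a call at kept against lost regions were 3.19 ± 0.516 (SD, n = 6) in K27M and 2.37 ± 0.468 (SD, n = 5) in WT tumours.

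Read changes of the 2 systems ran partly together. Over 1364 autosomal regions matched 1 to 1, the log2 folds of tumours and hindbrain neurospheres correlated at r = 0.438 (Spearman's rho 0.440) across regions, which are not independent replicates. Past the threshold in both were 141 regions, of which 113 rose in both, 16 fell in both and 12 went opposite ways. Independent lists would share 45.6 rising and 10.5 falling regions. In both systems the regions that rose were denser in WT than those that fell. The medians were 8.41 against 6.92 CPM per kb in tumours and 7.22 against 4.10 in hindbrain. Neither the correlation nor the independent lists were adjusted for density, so a common dependence on it was not separated from a shared change. The comparisons share no library.

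A hypothesis was that the same regions are affected in tumours and neurospheres. The odds of a call at kept against lost regions differed between genotypes (exact permutation p = 0.0238, adjusted 0.0404 over 14 measures), and the difference held with 60 Mb of densest islands in each tumour (p = 0.0108, adjusted 0.0216), which argues against unequal island length as the whole cause. These values go with a partly shared pattern, found and tested on the same tumours. Whether it follows from the width or density of the regions was not tested.

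Another hypothesis was that H3K27ac moves into regions that lose H3K27me3 in K27M neurospheres. The lost regions held 1.06% ± 0.088 (SD, n = 6) of autosomal H3K27ac length in K27M and 1.06% ± 0.0693 (SD, n = 5) in WT tumours (exact permutation p = 0.97), so no gain was found in tumours. H3K27ac was not profiled in neurospheres. In tumours these regions were not shown to lose H3K27me3 (log2 difference -0.22, exact permutation p = 0.392), so the test cannot decide the hypothesis. At the H3K27ac regions shared by all tumours, neurosphere islands covered 2.42% to 2.91% of the length in hindbrain K27M and 4.51% to 5.62% in hindbrain WT libraries, which is 1.52 to 1.61 and 0.729 to 0.774 times the share expected from island length. The effect of genotype on autosomal island length was not shown to differ between tumours and hindbrain neurospheres (log2 -0.24 and -1.92, exact permutation p = 0.0749 over 9240 arrangements, adjusted 0.28 over 7 such tests).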
